A study of Arabidopsis thaliana with 9 samples.

How the data were processed

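Small RNA libraries were made from Arabidopsis thaliana plants of 3 genotypes, Col-0 (LUC), prors1 (LUC) and rls6, with 3 libraries per genotype. Per the labels' protocols, plants grew for 25 days in long days of 16 h light and 8 h dark, 30 µg of total RNA was separated on a gel, RNA of 17 to 30 nt was taken, and libraries were made with a NEBNext small RNA kit. Another label gives an age of 26 days. Groups were taken from the sample titles and the genotype label. The source label instead gives both mutants names of the form rbp-ko. Which label is right about the genotypes could not be checked here. Per the submitters' processing notes, Trimmomatic, FastQC, Bowtie2 and featureCounts were used with the TAIR10 build. Their versions, roles and settings, and how reads with several mapping places or either strand were counted, are not given in the sources used here.

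The deposited table lists 37336 genes with a column per library. Its signal values are, as deposited by the authors, read counts per gene divided by a size factor per library, called normalized reads here. Every value was a whole multiple of the column's smallest value within 1e-06, so the whole reads behind them were recovered for 100% of values. They summed to 635738, 702303 and 613230 reads in replicates 1 to 3 of Col-0 (LUC), 633692, 611238 and 624598 in prors1 (LUC), and 655239, 679773 and 649353 in rls6. The size factors lay between 0.950 and 1.24. One gene, AT3G15920, held 13.0% to 22.3% of the reads of a library and the top 5 genes 26.3% to 37.0%, so the precision of other genes rests on the remaining reads.

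The same deposited table holds the authors' own comparison, with log2 fold changes, their standard errors on the log2 scale, a Wald score, p-values and adjusted p-values from DESeq2, per the file headers and the file's name. Its header names no groups. The log2 values followed prors1 (LUC) over Col-0 (LUC) (Pearson r 0.998 across 1770 genes, which are not independent replicates) and not rls6 over Col-0 (LUC) (r 0.534) or rls6 over prors1 (LUC) (r -0.256). The authors' deposited base mean, a signal value, needs at least 15 libraries in the fit to cover the sum of the 9 columns, so it was not used as a mean of these libraries. These columns served only for a comparison of calls.

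Genes were matched to the TAIR10.1 annotation, in which 37051 identifiers were found. The remaining 285 were organelle genes, known by their identifiers. Classes came from the annotated biotype and the organelle. A pseudogene here is thus a locus with that annotated biotype, which may include transposon loci. The reference holds 326 MIR genes and the table holds 0 of them, so microRNAs were measured only where a MIR gene overlaps a listed gene. Of 132 gene names in the fixed lists, 124 were found as symbols or synonyms in the reference, and all were matched by identifier.

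Replicate pairs of a genotype differed by more than sampling noise, with a chi-square per degree of freedom of 1.49 to 7.13 over genes with at least 20 reads, so no library was treated as a repeat of another. The planned main test for raw counts was edgeR's quasi-likelihood test. Since the table holds normalized values, the test planned for that case was used, limma 3.58.1 (R 4.3.3) with a mean-variance trend on log2(normalized reads + 1). It took all 9 libraries with genotype as the only term, 4766 genes with at least 10 normalized reads in at least 3 libraries, and a Benjamini-Hochberg adjusted p of 0.05 over these genes. Adjusted p-values without another named tool are from this fit. Log2 fold changes on this scale understate the change of genes with few reads, so means of normalized reads and their ratios are given beside them. Ratios to a group with 0 reads use a floor of 3 reads over the group. Intervals are 95% exact intervals for the ratio of recovered reads.

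Gene lists were tested with camera (limma, preset correlation 0.01) on the same log2 values rather than on voom weights as first planned, with Benjamini-Hochberg adjustment over the 8 lists with at least 5 tested members. The lists were the trans-acting siRNA loci, protein-coding loci that yield secondary siRNAs, RNA-directed DNA methylation components, microRNA and post-transcriptional silencing components, flowering-time genes, the RBP45 and RBP47 family, nuclear photosynthesis genes, floral organ, root hair, and anthocyanin and defence genes, 5 microRNA lists, tRNA, snoRNA, snRNA and rRNA genes, transposable element genes, pseudogenes, and chloroplast- and mitochondrion-encoded genes. Class shares, list sums and loci with few reads were compared with two-sided exact permutation tests (scipy 1.17.1), which cannot go below p = 0.1 with 3 libraries against 3.

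The genes named in the text followed a rule. PRORS1 and RBP45D were named whatever their values. In each comparison up to 8 genes with the largest and up to 8 with the smallest log2 fold change were named among those past adjusted p 0.05, with a mean of at least 5 CPM and no overlap between the libraries of the genotypes. In each list and comparison up to 3 called members with the smallest adjusted p were named or, where none was called, up to 2 with the highest mean. The most abundant loci and the examples in the closing section were chosen after their values were seen.

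The limma, edgeR and camera steps were tested on simulated data drawn from the real genes' means with known changes. For prors1 (LUC) against Col-0 (LUC), limma recovered 95 of 100 genes changed 2-fold and 100 of 100 changed 4-fold over 4723 genes, and called 16 of 4523 unchanged genes. For rls6 against prors1 (LUC) it recovered 96 and 100 and called 17. Unchanged genes thus made up 7.58% and 7.98% of limma's calls in these comparisons, and 5.37% and 6.34% of edgeR's. These shares were above the share of false calls that the adjusted p cut-off aims for, but the data were drawn only once, so an excess is not shown. For rls6 against Col-0 (LUC), where no change was simulated, limma called 0 of 4723 genes, as edgeR called 0 of 4770. Camera called 0 of 7 lists without a set effect in each comparison. The simulated genes were drawn independently, so this could not show false list calls that come from correlation between genes. The sharing of control libraries was simulated 100 times with unchanged groups, and 20 further simulations were fitted for shared calls.

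Alternatives planned ahead were RLE size factors, upper-quartile scaling, leaving out 914 organelle, rRNA and tRNA genes, a looser and a different count filter, DESeq2 1.42.0 (Wald test on recovered reads), fits with only the genotypes compared, the replicate number as a block, each library left out in turn, other pseudocounts, a minimum log2 fold change of 1, and for lists an estimated correlation and fry. The edgeR 4.0.16 quasi-likelihood test on recovered reads, TMM scaling, limma without a trend and, for counts and lists alone, upper-quartile factors over all genes were added after the data were seen. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. No library or column of library values was left out.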

Results

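Small RNAs of 17 to 30 nt were sequenced from soil-grown Arabidopsis thaliana plants of 3 genotypes, named Col-0 (LUC), prors1 (LUC) and rls6, with 3 libraries each. Col-0 is the standard laboratory accession. The titles and genotype labels do not say what LUC marks or which change rls6 carries. The source label gives both mutants names of the form rbp-ko. The design text asks how small RNA accumulation in the mutants compares with that in Col-0 (LUC). The title of the series names RBP45D, an RNA-binding protein, together with flowering time and RNA-directed DNA methylation, the pathway in which small RNAs guide methylation of matching DNA. The libraries held between 611238 and 702303 reads over annotated genes. Each library had reads at 13649 to 15793 of the 37336 genes. Of these, 4766 had enough reads to be tested.

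The 5 loci with most reads took 26.3% to 37.0% of the reads of a library. AT3G15920, a Phox-domain protein gene with the small nucleolar RNA gene AT3G03175 on its opposite strand, took from 13.0% to 22.3% of the reads of a library. TAS1C, TAS2 and TAS1A, whose transcripts are cut by a microRNA and turned into trans-acting siRNAs, took 4.11%, 3.31% and 2.86% of all reads. Among these 4 loci the smallest adjusted p over the 3 comparisons was 0.0912, for TAS1A in rls6 against Col-0 (LUC). CPA (AT3G05520), an actin capping protein gene with the tRNA gene AT3G05525 opposite to it, averaged 17271 normalized reads in Col-0 (LUC), 39766 in prors1 (LUC) and 22402 in rls6. Its log2 fold change was 1.29 in prors1 (LUC) against Col-0 (LUC) (adjusted p = 0.000163) and -0.83 in rls6 against prors1 (LUC) (adjusted p = 0.00825). Reads of genes on opposite strands cannot be told apart here.

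Small RNA reads at the genes named in the labels and the title were few. PRORS1 (AT5G52520, named OVA6 in the reference), which encodes the organellar prolyl-tRNA synthetase, lies on chromosome 5 at 21311020 to 21314180 in TAIR10.1. It had 1 read over the 3 Col-0 (LUC) libraries, 16 over the prors1 (LUC) libraries and 21 over the rls6 libraries. Replicates 1 to 3 of prors1 (LUC) had 8, 5 and 3 reads, and each rls6 library had 7. The ratio to Col-0 (LUC) was 20.3 in prors1 (LUC) (95% counting interval 2.87 to 774) and 24.8 in rls6 (3.65 to 938). Intervals of this kind cover counting error only. The exact permutation test (two-sided, 3 against 3) gave p = 0.1 for both, the smallest p this design allows. After Benjamini-Hochberg adjustment over 6 such tests p was 0.15. In the authors' deposited comparison, which followed prors1 (LUC) over Col-0 (LUC), PRORS1 had a log2 fold change of 1.33 ± 0.42 (SE). Its DESeq2 adjusted p there was 0.0301. RBP45D (AT5G19350, chromosome 5, 6518777 to 6521483) had 1 read in all, in prors1 (LUC). Small RNA reads do not measure mRNA, so these values do not check the genotypes.

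Against Col-0 (LUC), prors1 (LUC) had far more small RNA at AT1G29910 (CAB3), a light-harvesting chlorophyll a/b-binding protein gene on chromosome 1 at 10472280 to 10473502. Its normalized reads averaged 1036 ± 168 (SD, n = 3) in prors1 (LUC) and 3.07 ± 1.78 in Col-0 (LUC), a ratio of 337, with a log2 fold change of 8.10 ± 0.24 (SE, adjusted p = 9.17e-17). The chloroplast-encoded genes rose as a group, 76 of 106 tested members being higher and 2 lower, with a median log2 fold change of 0.81, a group call that was not kept with an estimated correlation between genes (camera adjusted p = 0.0679). AT3G25795 (TAS4), a trans-acting siRNA locus on chromosome 3 at 9417551 to 9418705, fell from 2326 ± 197 to 512 ± 61.7 normalized reads, a log2 fold change of -2.18 ± 0.10 (adjusted p = 2.63e-13). Reads at AT1G51150 (DEG6), a protease gene, fell from 98.5 ± 19.1 to 0.321 ± 0.556, a fold of 306 with a counting interval of 51.2 to 11373.

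Other large rises in prors1 (LUC) were found at loci of several kinds. SIG2 (AT1G08540), a sigma factor of the plastid RNA polymerase, had 70 reads in prors1 (LUC) and 0 in Col-0 (LUC), at least 26.6-fold higher against a floor of 3 reads over the group. The uncharacterized gene AT1G28005 was at least 13.7-fold higher by the same floor. AT4G14810, with the microRNA gene MIR780 on its opposite strand, rose from 15.7 ± 2.38 to 221 ± 38.7 normalized reads. The long non-coding RNA gene AT1G07887 rose 34.1-fold and the pentatricopeptide repeat gene AT1G20300 rose 11.3-fold. The pseudogene AT3G56275 rose 23.1-fold. The pseudogene AT2G19200 had 164 reads against 3, a ratio of 67.7 with a counting interval of 21.2 to 309. All of these had adjusted p of 1.19e-07 or less.

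The largest falls in prors1 (LUC) reached loci with almost no reads left. AT1G70080, a terpenoid cyclase gene, had 171 reads in Col-0 (LUC) and 0 in prors1 (LUC), at least 49.5-fold lower. LCR26 (AT4G29290), which encodes a small cysteine-rich protein, was at least 25.4-fold lower. AT5G43755, annotated as similar to a retroelement reverse transcriptase, fell from 185 ± 19.5 to 4.05 ± 3.71 normalized reads. The long non-coding RNA genes AT2G06995 (-5.43) and AT3G51238 (-5.08) and the acyltransferase gene AT3G50300 (-4.04) also fell, by the log2 fold changes given. AT4G03038 fell from 278 ± 89.1 to 8.17 ± 2.37, and its annotation overlaps MIR826b on the same strand and MIR826a on the opposite strand. The largest adjusted p among these 7 loci was 1.97e-06.

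In all, 685 of 4766 tested genes passed adjusted p 0.05 in prors1 (LUC) against Col-0 (LUC) with limma, 369 higher and 316 lower. Of these, 123 were at least 2-fold higher and 113 at least 2-fold lower on the log2(normalized reads + 1) scale. DESeq2 called fewer genes, 305, and limma without a trend called 429. Without Col-0 (LUC) replicate 3 the number lower was 202. With upper-quartile factors over all genes, a scaling added after seeing the data, 632 were higher and 137 lower. Nothing in the labels says that libraries of a genotype came from separate plants, so p-values measure only the spread between these libraries.

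**Figure D1:**
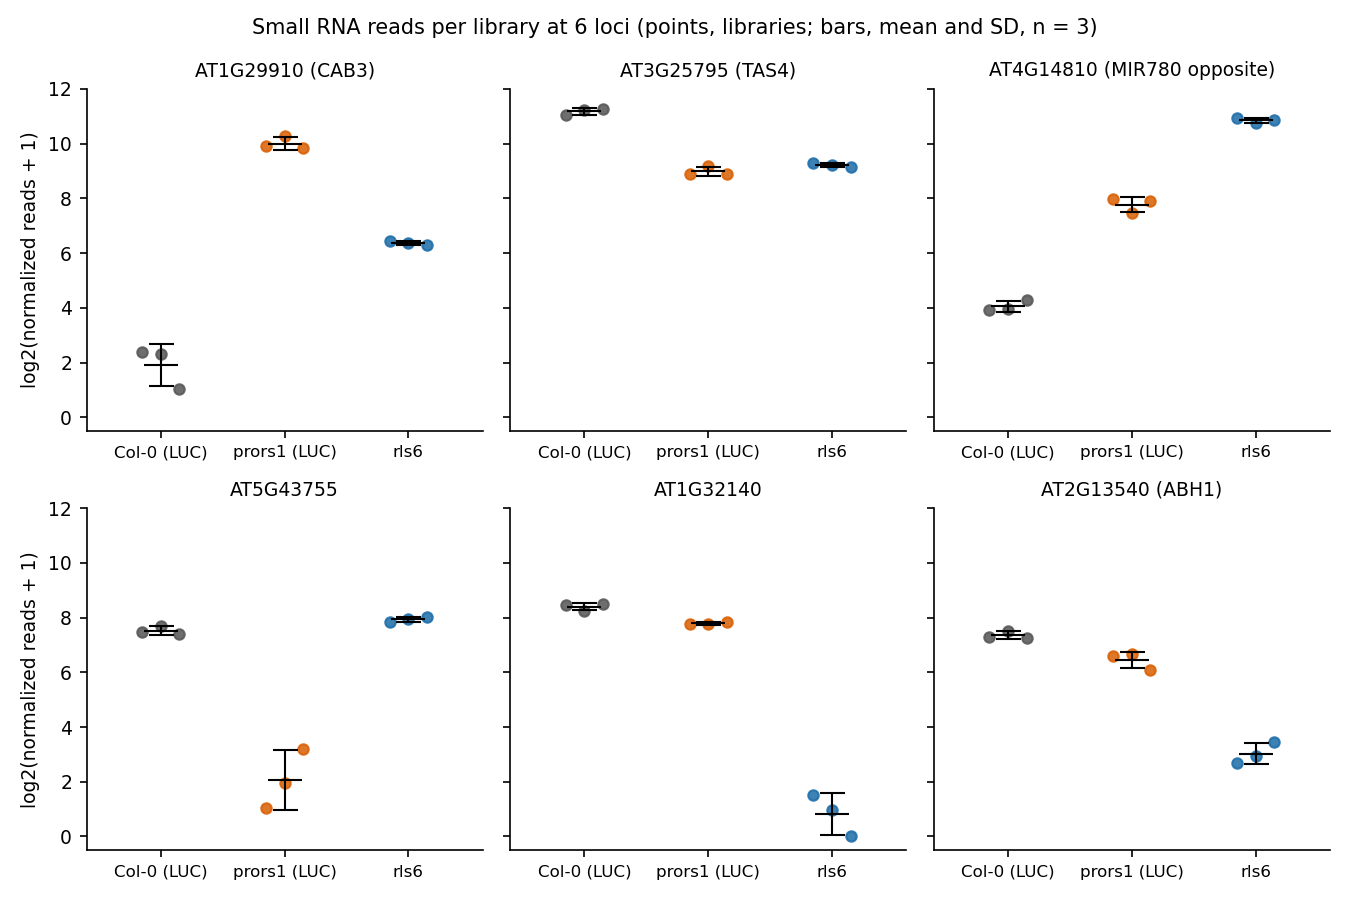
Normalized small RNA reads per library, on the log2(normalized reads + 1) scale, at 6 loci, with points for libraries and bars for the mean and SD of the 3 libraries of a genotype. AT1G29910 (CAB3) averaged 3.07, 1036 and 81.5 normalized reads in Col-0 (LUC), prors1 (LUC) and rls6.

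Among the gene lists fixed before the data were examined, the chloroplast-encoded genes stood apart in prors1 (LUC) (camera adjusted p = 5.91e-44), with 88 higher and 3 lower when adjusted over the list alone. That call was not kept with an estimated correlation between genes (adjusted p = 0.0679 with an estimated correlation, the highest of 3 alternatives, which began at 1.21e-45). ATCG00660 rose 8.33-fold to 314 ± 15.2 normalized reads and ATCG00020 rose 5.74-fold to 543 ± 104. The mitochondrion-encoded genes had a median log2 fold change of 0.41, with 5 of 34 tested members higher and 1 lower (7 and 1 adjusted over the list alone). The number higher was 2 without Col-0 (LUC) replicate 1, Col-0 (LUC) replicate 3 or prors1 (LUC) replicate 1, and 3 without prors1 (LUC) replicate 3. With upper-quartile factors over all genes 13 were higher and 0 lower, with a median of 0.60. Their camera adjusted p was 0.00125, and adjusted p = 0.0679 with an estimated correlation (0.000856 to 0.0679 over 3 alternatives). Among them ATMG01090 rose by a log2 fold change of 0.79 (adjusted p = 0.000999), while ATMG00030, the most abundant, fell by 0.43 on the log2 scale (adjusted p = 0.00745, and 0.0539 without prors1 (LUC) replicate 2, the range over 21 settings being 1.5e-13 to 0.109). The summed reads of the class were 2556 ± 225 against 2584 ± 76.6 and so did not rise with the median. Much of that sum is ATMG00030, with 1389, 998 and 1143 normalized reads in prors1 (LUC) and 1573, 1460 and 1683 in Col-0 (LUC). The level sum therefore does not show that the other members stayed level.

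The nuclear photosynthesis genes had 2 of 5 tested members higher and none lower in prors1 (LUC), also 2 adjusted over the list alone (camera adjusted p = 0.0102, and adjusted p = 0.0679 with an estimated correlation, within 6.69e-06 to 0.0679 over 4 alternatives). The median of the list was 0.14, its mean 2.18, and the median -0.10 without prors1 (LUC) replicate 2. The members called were CAB3 and its neighbour CAB2 (AT1G29920), which encode the same kind of protein. CAB2 rose 14.1-fold to 21.1 ± 4.62 normalized reads (adjusted p = 2.21e-05). Of the 21-base windows of CAB3, 57.4% occur once in the reference genome, so reads from the rest could be assigned to another copy of the gene. The other 24 genes of the list together had 94.0 ± 6.55 normalized reads in prors1 (LUC) and 70.8 ± 6.27 in Col-0 (LUC). These 24 include CAB2, whose rise from 1.50 to 21.1 normalized reads makes up most of this difference.

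Of the 8 trans-acting siRNA loci tested, TAS4 fell and the other 7 did not pass the test in prors1 (LUC), with 2 lower when adjusted over the list alone (camera adjusted p = 0.215, fry adjusted p = 0.00169). Over all genes 2 were lower without prors1 (LUC) replicate 1 or rls6 replicate 2, and 2 lower and 1 higher without Col-0 (LUC) replicate 2. Of 24 tested protein-coding loci that yield secondary siRNAs, 2 were higher and 2 lower, or 3 and 2 adjusted over the list alone (camera adjusted p = 0.215, and 0.0313 without Col-0 (LUC) replicate 1, against 0.226 to 0.687 over 4 other alternatives). The auxin receptor gene AFB2 (AT3G26810) had a log2 fold change of -0.79 ± 0.12 (adjusted p = 7.85e-05), and the disease resistance gene AT5G38850 rose from 1933 ± 176 to 2623 ± 88.2 (adjusted p = 0.00196, and 0.0527 without a trend). The disease resistance gene AT5G43740 had a log2 fold change of 0.30 (adjusted p = 0.0277), whose call was lost without Col-0 (LUC) replicate 1 (adjusted p = 0.115) or without prors1 (LUC) replicate 1, 2 or 3 (0.0596, 0.0816 and 0.0582), within 0.0135 to 0.162 over 22 settings.

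Among 5 tested members of the microRNA and post-transcriptional silencing list, 1 was higher and 1 lower in prors1 (LUC), also when adjusted over the list alone (camera adjusted p = 0.661). DCL4, the enzyme that cuts trans-acting siRNAs, had a log2 fold change of 0.83 (adjusted p = 0.0329), with adjusted p of 0.0836 and 0.125 without Col-0 (LUC) replicates 1 and 3 and 0.101 and 0.219 without prors1 (LUC) replicates 1 and 2, within 0.00233 to 0.219 over 22 settings. AGO1, the main microRNA effector, had -0.57 (adjusted p = 0.0375), and adjusted p was between 0.0507 and 0.151 without Col-0 (LUC) replicate 2 or 3, prors1 (LUC) replicate 1 or 3, or rls6 replicate 1 or 3, within 0.0125 to 0.507 over the 22 settings. Of the 5 tested snRNA genes limma called 0 in prors1 (LUC), over all genes or adjusted over the list alone, with 1 at an unadjusted p below 0.05 and 0 called by edgeR or DESeq2. Their median was -0.17, their mean 0.02 and camera adjusted p = 0.891. The median was -0.40 without Col-0 (LUC) replicate 1, and turned to 0.02 without Col-0 (LUC) replicate 3 and to 0.04 without prors1 (LUC) replicate 2. The 2781 tested pseudogenes had 84 higher and 115 lower (47 and 47 adjusted over the list alone), with a median log2 fold change of -0.00 and camera adjusted p = 0.231. With upper-quartile factors over all genes 214 were higher and 22 lower, with a median of 0.18. Without Col-0 (LUC) replicate 1 there were 68 lower, without Col-0 (LUC) replicate 3 51 higher and 51 lower, without prors1 (LUC) replicate 2 49 higher and 75 lower, and without prors1 (LUC) replicate 3 54 higher.

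**Figure D2:**
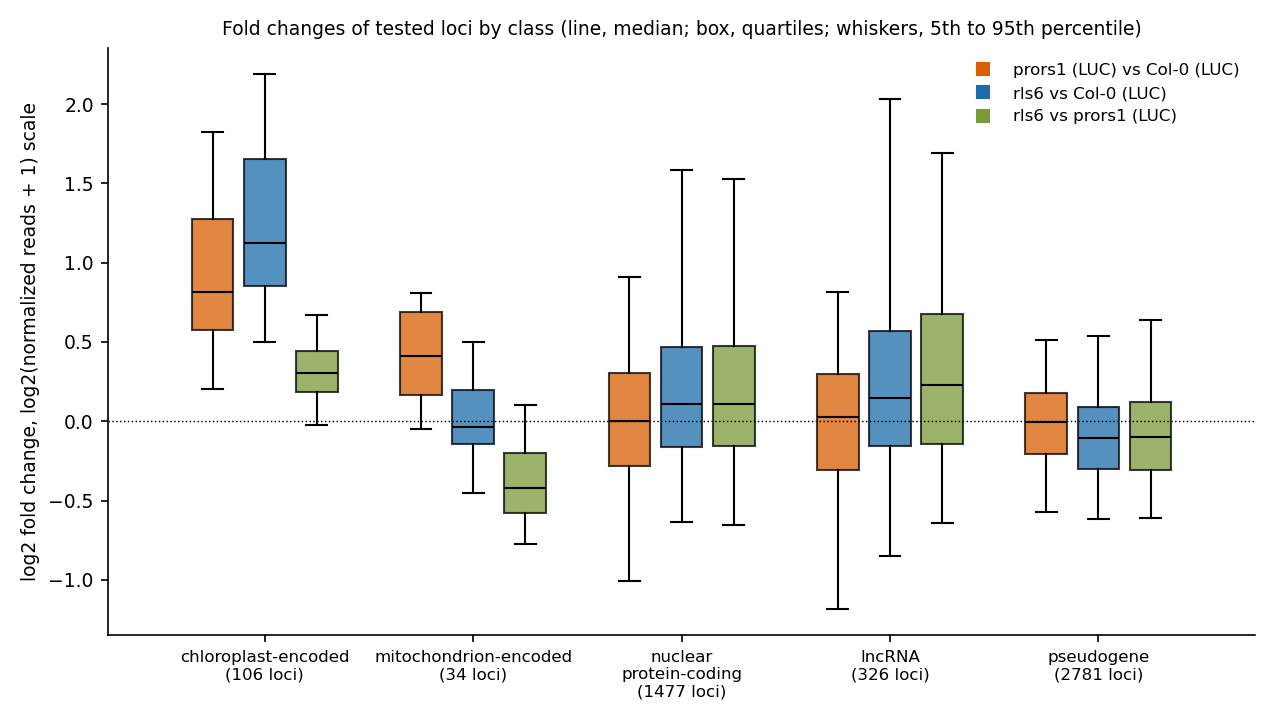
Log2 fold changes of the tested loci of 5 classes in the 3 comparisons, on the log2(normalized reads + 1) scale, with lines at medians, boxes over the quartiles and whiskers over the central 90% of loci. The chloroplast-encoded genes had medians of 0.81 and 1.12 in prors1 (LUC) and rls6 against Col-0 (LUC).

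Against Col-0 (LUC), the largest rise in rls6 among the named genes on the log2(normalized reads + 1) scale was at AT4G14810. This is the locus with MIR780 on its opposite strand (chromosome 4). It averaged 1848 ± 105 normalized reads (n = 3) against 15.7 ± 2.38, a ratio of 118 and a log2 fold change of 6.80 ± 0.13 (adjusted p = 6.71e-21). CAB3 rose here too, to 81.5 ± 3.47 normalized reads, 26.5-fold over Col-0 (LUC) (adjusted p = 1.93e-12). Of the chloroplast-encoded genes 97 of 106 were higher and 3 lower, with a median log2 fold change of 1.12, and this group call was not kept with an estimated correlation either (camera adjusted p = 0.064). TAS4 fell to 596 ± 34.8 normalized reads (log2 fold change -1.96 ± 0.10, adjusted p = 9.18e-13). The F-box gene AT1G32140 fell from 336 ± 30.2 to 0.925 ± 0.916, a fold of 364 with a counting interval of 120 to 1712.

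Further large rises in rls6 included AT1G28000 and AT1G28005, which overlap on opposite strands of chromosome 1, so that their reads cannot be told apart. The pentatricopeptide repeat gene AT1G28000 had 149 reads against 2 in Col-0 (LUC) (ratio 86.6, counting interval 21.9 to 671), and AT1G28005 was at least 43.6-fold higher. The long non-coding RNA gene AT3G05025 rose 64.7-fold to 132 ± 3.87 normalized reads. Of 4 loci with 1 to 3 reads in Col-0 (LUC), the thaumatin-like gene AT5G40020 had a ratio of 142 (23.0 to 5207), the long non-coding RNA gene AT1G06417 127 (21.3 to 4822), the gene AT2G36810 117 (19.5 to 4438) and the pseudogene AT2G19200 57.5 (18.1 to 265). The largest adjusted p among these 7 loci was 7.69e-08.

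Falls in rls6 shared several loci with prors1 (LUC). DEG6 had 0 reads in rls6, at least 104-fold lower than in Col-0 (LUC). AT1G70080 had 1 read against 171, a fold of 160 (28.0 to 6286), and AT3G51238 fell 40.9-fold. LCR26 had 2 reads against 87, a fold of 38.9 (10.8 to 338), and AT2G06995 fell 19.0-fold. ABH1 (AT2G13540), the large subunit of the nuclear cap-binding complex, fell from 164 ± 16.0 to 7.34 ± 2.30 normalized reads (log2 fold change -4.34 ± 0.19, adjusted p = 1.3e-13). AT4G12820, an F-box gene, had 3 reads against 152, a fold of 47.0 (15.7 to 230). The largest adjusted p among these loci was 4.63e-06.

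With limma, 841 of 4766 genes passed adjusted p 0.05 in rls6 against Col-0 (LUC), 605 higher and 236 lower. Among them, 325 were at least 2-fold higher and 60 at least 2-fold lower. DESeq2 called 503, 428 higher and 75 lower. The number lower was 134 without Col-0 (LUC) replicate 3 and 151 without rls6 replicate 2. The share of calls that were higher, 71.9%, was 85.1% with DESeq2 and 54.8% with upper-quartile scaling, which gave 527 higher and 435 lower and moved the median log2 fold change of all tested genes from -0.02 to -0.11. Upper-quartile factors over all genes, added after seeing the data, gave 1104 higher and 67 lower.

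The chloroplast-encoded genes stood apart in rls6 (camera adjusted p = 1.83e-47, and adjusted p = 0.064 with an estimated correlation, the highest of 3 alternatives, which began at 6.51e-49), with 101 higher and 3 lower when adjusted over the list alone. ATCG00660 rose from 37.7 ± 2.22 to 454 ± 9.65 normalized reads and ATCG00020 rose 7.10-fold to 672 ± 95.1. Of the 34 mitochondrion-encoded genes limma called 0 in rls6, over all genes or adjusted over the list alone, with 4 at an unadjusted p below 0.05 and 0 called by edgeR or DESeq2. Their median log2 fold change was -0.03, their mean 0.01 and camera adjusted p = 0.735. The median was 0.02 without Col-0 (LUC) replicate 2, where 2 were higher, and 0.02 without rls6 replicate 2, and 1 was lower without prors1 (LUC) replicate 2. The most abundant of them, ATMG00030, had 1410 ± 51.0 normalized reads against 1572 ± 112 (adjusted p = 0.368). Pseudogenes went down as a group against the other genes (camera adjusted p = 1.82e-09, and adjusted p = 0.000125 with an estimated correlation, within 2.07e-09 to 0.00122 over 4 alternatives), by a median log2 fold change of -0.10, with 124 of 2781 higher and 133 lower (108 and 74 adjusted over the list alone). The highest of these, fry adjusted p = 0.00122, is for a change of the list itself and not against the other genes. The nuclear protein-coding genes had a median of 0.11. The summed normalized reads of all annotated pseudogenes hardly differed, with 192460 ± 1350 in rls6 and 194536 ± 1733 in Col-0 (LUC), a ratio of 0.989 (exact permutation p = 0.2). The number lower was 79 and 66 without Col-0 (LUC) replicates 1 and 3, 83, 74 and 87 without rls6 replicates 1, 2 and 3, and 291 with upper-quartile scaling, where 99 were higher and the median was -0.19. That direction turned with upper-quartile factors over all genes, a scaling added after seeing the data, to a median of 0.17 with 338 higher and 10 lower, below the median of 0.26 over all tested genes. The pseudogenes with the smallest adjusted p rose, however. These were AT3G43832 (8.30-fold, to 596 ± 34.9), AT1G77095 (7.41-fold) and AT5G39205 (5.94-fold).

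Camera called none of the other lists in rls6 against Col-0 (LUC), while fry called the nuclear photosynthesis genes (adjusted p = 0.000245). Of 5 tested nuclear photosynthesis genes, CAB3 and the photosystem I antenna gene LHCA2 (14.3 ± 5.46 to 34.4 ± 3.74, adjusted p = 0.00192) rose, and these 2 also passed adjusted over the list alone (camera adjusted p = 0.0996, and 0.0376 without Col-0 (LUC) replicate 3, against 0.000245 to 0.208 over 4 other alternatives). Among 8 trans-acting siRNA loci, TAS4 fell and TAS3b (AT5G49615) rose from 86.2 ± 8.94 to 147 ± 4.52 normalized reads (adjusted p = 3.02e-05), the same counts as adjusted over the list alone, and 2 were higher without Col-0 (LUC) replicate 2 or prors1 (LUC) replicate 2. The median of that list was 0.10 and its mean -0.07 (camera adjusted p = 0.991). Of 24 secondary siRNA loci, 2 were higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.684), among them AT5G38850 (log2 fold change 0.50, adjusted p = 0.00035). Of these loci 5 were higher and 0 lower with upper-quartile factors over all genes.

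Some calls of smaller size in rls6 were lost without 1 of the libraries. The disease resistance gene AT5G63020 had a log2 fold change of 0.66 (adjusted p = 0.0182, and 0.0891, 0.0589 and 0.117 without Col-0 (LUC) replicate 1, Col-0 (LUC) replicate 2 or rls6 replicate 2, within 0.00393 to 0.249 over 22 settings). AFB2 had -0.39 (adjusted p = 0.0279, and 0.0504 to 0.155 without Col-0 (LUC) replicate 1 or 3 or rls6 replicate 1 or 3, within 0.00636 to 0.306 over the settings). The snRNA list had a median of 0.47, and -0.08 without Col-0 (LUC) replicate 1. Among its 5 tested genes (2 higher, also adjusted over the list alone, camera adjusted p = 0.684), U6.5 rose from 14.8 ± 2.13 to 29.2 ± 4.18 (adjusted p = 0.00525, and 0.134 with DESeq2). U1.3 had 1.23 (adjusted p = 0.0372), which lay between 0.0527 and 0.204 without Col-0 (LUC) replicate 1 or 3 or any rls6 replicate, within 0.014 to 0.28 over the settings. Of the 5 silencing components limma called 0, over all genes or adjusted over the list alone, with 0 at an unadjusted p below 0.05 and 0 called by edgeR or DESeq2 (camera adjusted p = 0.991). AGO2, the most abundant of them, had 6701 ± 1334 against 5999 ± 1556 normalized reads (adjusted p = 0.525). AGO3 had a log2 fold change of 0.28 (adjusted p = 0.543, and 0.045 without Col-0 (LUC) replicate 2, the highest over the settings being 0.994).

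The test between rls6 and prors1 (LUC) asks at which loci the mutants differ. AT5G43755, which had almost lost its small RNAs in prors1 (LUC), had 244 ± 17.7 normalized reads in rls6 against 4.05 ± 3.71 (log2 fold change 5.87 ± 0.31, adjusted p = 2.9e-12), near the 185 ± 19.5 of Col-0 (LUC). CAB3 was 12.7-fold lower in rls6 than in prors1 (LUC) (log2 fold change -3.64 ± 0.24, adjusted p = 8.4e-11), and CAB2 had 3 reads against 63, a fold of 22.2 (7.33 to 112). AT1G32140 had a log2 fold change of -6.97 ± 0.24 (adjusted p = 3.13e-15), its level in prors1 (LUC) being 220 ± 9.23. TAS4 did not pass the test between the mutants (log2 fold change 0.22, adjusted p = 0.136).

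Further loci with more small RNA in rls6 than in prors1 (LUC) had few or no reads in prors1 (LUC). AT1G06417 was at least 35.0-fold higher, and AT3G05025 was 28.0-fold higher. AT5G40020 had 121 reads against 3, a ratio of 36.5 (12.6 to 186). The pseudogene AT3G23645 was at least 16.8-fold higher, and the kinase-like gene AT3G23650, which lies beside it on the same strand, had 89.0 ± 7.48 against 4.45 ± 2.23 normalized reads. The pseudogene AT5G41494 had 67 reads against 1, a ratio of 60.2 (10.9 to 2517), and AT5G39370, a lectin-like gene that overlaps MIR3933 on the same strand, was at least 16.1-fold higher. The largest adjusted p among these loci was 1.32e-05.

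Loci with less small RNA in rls6 than in prors1 (LUC) included ABH1 (87.9 ± 17.6 to 7.34 ± 2.30) and the invertase and pectin methylesterase inhibitor gene AT5G46930 (191 ± 14.5 to 37.7 ± 7.32). The F-box gene AT4G12820 had 3 reads against 21, a fold of 7.54 (2.23 to 39.1), and the long non-coding RNA gene AT3G03945 was 4.79-fold lower. The F-box gene AT3G19880 had 1.57 ± 2.72 against 10.4 ± 1.06 normalized reads (adjusted p = 0.00134). DESeq2 did not call this gene (adjusted p = 0.0558), and over 21 settings its adjusted p lay between 2.93e-08 and 0.0558.

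In all, 802 of 4766 genes passed adjusted p 0.05 between rls6 and prors1 (LUC) with limma, 556 higher and 246 lower in rls6, of which 277 and 49 differed at least 2-fold. DESeq2 called 419 (355 and 64), and the number lower was 160 without rls6 replicate 3. The higher share of 69.3% became 84.7% with DESeq2 and 54.9% with upper-quartile scaling (480 higher and 394 lower). With upper-quartile factors over all genes 603 were higher and 97 lower.

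Neither organelle group call between the mutants was kept with an estimated correlation between genes. The mitochondrion-encoded genes were lower in rls6 than in prors1 (LUC) by a median log2 fold change of -0.42, with 6 of 34 lower and none higher, or 11 and 1 adjusted over the list alone (camera adjusted p = 0.000184, and adjusted p = 0.0519 with an estimated correlation, within 0.00028 to 0.0519 over 3 alternatives). The number lower was 3 without rls6 replicate 2 or 3 or with upper-quartile factors over all genes, and 12 with upper-quartile scaling. ATMG01090 fell from 134 ± 9.51 to 83.8 ± 10.6 normalized reads (adjusted p = 0.00317). ATMG00140 had -1.13 (adjusted p = 0.018, and 0.104 and 0.0555 without prors1 (LUC) replicate 3 or rls6 replicate 3, within 0.0035 to 0.292 over 20 settings). ATMG01300 had -1.12 (adjusted p = 0.0243, and 0.0898, 0.102 and 0.157 without prors1 (LUC) replicate 1, prors1 (LUC) replicate 2 or rls6 replicate 3, within 0.00667 to 0.265 over 21 settings). The chloroplast-encoded genes were higher by a median of 0.30, with 14 of 106 higher and none lower, also adjusted over the list alone (camera adjusted p = 3.5e-06, and adjusted p = 0.498 with an estimated correlation, within 1.73e-06 to 0.498 over 3 alternatives). ATCG00120 was 1.60-fold and ATCG00660 1.45-fold higher. Without prors1 (LUC) replicate 2 the median was 0.16, with 6 higher and 1 lower. The number higher was also 6 without rls6 replicate 3, 8 without prors1 (LUC) replicate 3 and 24 without prors1 (LUC) replicate 1.

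Pseudogenes were lower in rls6 than in prors1 (LUC) by a median log2 fold change of -0.10 (camera adjusted p = 3.2e-07, and adjusted p = 0.000261 with an estimated correlation, within 3.18e-07 to 0.00279 over 4 alternatives), although 164 were higher and 149 lower (144 and 109 adjusted over the list alone). Their summed normalized reads were 192460 ± 1350 in rls6 and 195876 ± 760 in prors1 (LUC), a ratio of 0.983 (exact permutation p = 0.1, adjusted p = 0.283). The number lower was 93 and 91 without prors1 (LUC) replicates 1 and 3, 98 and 87 without rls6 replicates 1 and 3, and 269 with upper-quartile scaling, where 135 were higher and the median was -0.17. With upper-quartile factors over all genes, added after seeing the data, the median was -0.00, with 174 higher and 35 lower, against 0.07 over all tested genes. AT3G43832 rose 7.28-fold, AT1G77095 7.67-fold and AT2G45090 4.98-fold. The pseudogene calls in rls6, against either genotype, were the only list calls of camera that held with an estimated correlation.

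Camera called none of the remaining lists between the mutants, while fry called the nuclear photosynthesis genes (adjusted p = 0.000125) and the trans-acting siRNA loci (adjusted p = 0.00818). Of 5 nuclear photosynthesis genes, CAB3 and CAB2 fell and LHCA2 rose (adjusted p = 0.000933), also adjusted over the list alone. The median was 0.28 and the mean -1.03 (camera adjusted p = 0.159), and the median was -0.02 and -0.09 without prors1 (LUC) replicates 2 and 3. TAS3b rose 1.46-fold (adjusted p = 0.00218), the 1 call of limma among 8 trans-acting siRNA loci, also adjusted over the list alone (camera adjusted p = 0.159). DESeq2 called 2 of the 8, and limma called 2 as higher without prors1 (LUC) replicate 2. Of 24 secondary siRNA loci limma called 2 as higher and 0 adjusted over the list alone (camera adjusted p = 0.588), with 3 at an unadjusted p below 0.05, 1 called by edgeR and 0 by DESeq2. The pair called were AFB2 (0.39, adjusted p = 0.0292) and AGO1 (0.54, adjusted p = 0.0446). AFB2 lay between 0.0525 and 0.113 without any prors1 (LUC) replicate or rls6 replicate 2 or 3, within 0.0181 to 0.337 over 22 settings. AGO1 lay between 0.0502 and 0.175 without Col-0 (LUC) replicate 3, prors1 (LUC) replicate 1 or 3, or any rls6 replicate, within 0.0133 to 0.518.

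DCL4, with AGO1 the other called member of the 5 silencing components (1 higher and 1 lower, also adjusted over the list alone, camera adjusted p = 0.588), had -0.79 between the mutants (adjusted p = 0.0363, and 0.0568 to 0.238 without prors1 (LUC) replicate 1 or 2 or any rls6 replicate, within 0.00222 to 0.238 over 22 settings). Of 5 snRNA genes, U1.3 had 1.54 (adjusted p = 0.00934, and 0.056 without rls6 replicate 2, within 0.000551 to 0.126), the 1 call also adjusted over the list alone (camera adjusted p = 0.565). The median of the list was 0.30, and 0.08 without rls6 replicate 2.

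Several fixed lists had too few tested members for a set test, and their summed normalized reads were compared by exact permutation tests instead. The 24 RNA-directed DNA methylation components had 22.5 ± 4.89 normalized reads in Col-0 (LUC), 16.0 ± 6.36 in prors1 (LUC) and 22.6 ± 5.40 in rls6. The 20 flowering-time genes had 69.0 ± 15.1, 68.6 ± 2.62 and 75.3 ± 2.37, most of them at FVE (AT2G19520; adjusted p = 0.799 in prors1 (LUC) and 0.563 in rls6 against Col-0 (LUC)). The 8 genes of the RBP45 and RBP47 family had 2.25 ± 2.49, 1.34 ± 0.513 and 2.61 ± 3.04. Small RNA reads at marker genes of other tissues were few, with 22 over all libraries at 8 floral organ genes and 9 at 6 root hair genes. Since small RNA reads do not measure mRNA, these counts do not check the tissue. The 7 anthocyanin and defence genes had 26 reads. The 287 snoRNA genes had 188 ± 27.1, 159 ± 5.00 and 251 ± 9.43, and the snoRNA gene AT1G06667 rose from 34.9 ± 4.63 to 85.4 ± 16.3 in rls6 against Col-0 (LUC) (adjusted p = 1.12e-05).

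The 625 tRNA genes had 136 ± 8.43, 122 ± 17.0 and 149 ± 7.87 normalized reads in Col-0 (LUC), prors1 (LUC) and rls6, and of 3 tested members limma, edgeR and DESeq2 called 0, with 0 at an unadjusted p below 0.05. The 4 rRNA genes had 63.3 ± 9.55, 78.1 ± 6.18 and 54.5 ± 9.17. The rRNA gene AT2G01020 was lower in rls6 than in prors1 (LUC) (log2 fold change -0.51, adjusted p = 0.0257), with adjusted p of 0.0846, 0.07, 0.146 and 0.0543 without prors1 (LUC) replicates 2 and 3 and rls6 replicates 1 and 3, within 0.011 to 0.325 over 21 settings. No exact test of these sums went below p = 0.1, the smallest 3 against 3 can give, and none was below 0.283 after Benjamini-Hochberg adjustment. The 5 microRNA lists and the list of transposable element genes had 0 members in the table. Members were sought by annotation labels alone. Transposon loci annotated under another class, such as pseudogenes, therefore cannot be told apart here.

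By share of reads, the chloroplast-encoded genes took 2.45% ± 0.0401 (SD, n = 3) of Col-0 (LUC) reads, 3.85% ± 0.402 of prors1 (LUC) reads and 4.56% ± 0.0542 of rls6 reads. The mitochondrion-encoded genes took 0.451% ± 0.0296, 0.404% ± 0.0136 and 0.389% ± 0.0215. Pseudogenes took 34.0% ± 2.85, 31.1% ± 1.99 and 30.7% ± 1.41, and nuclear protein-coding genes 43.0% ± 2.87, 46.5% ± 3.29 and 44.1% ± 1.57. The exact permutation test over 10 classes and 3 comparisons, 30 tests in all, reached its smallest p of 0.1 at best and 0.25 after Benjamini-Hochberg adjustment. In 12 of the 30 the genotypes did not overlap, where chance gives 10% of such pairs.

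Both mutants shared many changes against the same Col-0 (LUC) libraries. Of the genes higher in prors1 (LUC) 230 were also higher in rls6, where independent lists of these sizes would share 46.8, and 90 were lower in both, where independent lists would share 15.6. Among these, CAB3 and AT4G14810 were higher in both, and DEG6, AT1G70080 and TAS4 were lower in both. The chloroplast-encoded genes, which rose as a group, gave 76 of the 369 higher calls in prors1 (LUC) and 97 of the 605 in rls6. The numbers for independent lists take no account of genes that change together, so the 230 are not that many separate changes. Across genes, which are not independent replicates, the log2 fold changes of the mutants had a Pearson r of 0.566. Unchanged groups simulated against the same controls gave a mean r of 0.479 (highest 0.51 of 100). They shared 0 calls in 20 fits, but unchanged groups have next to no calls to share, so this is no measure for the 230 and 90. The covariance was 0.228, against 0.0306 simulated, a difference of 0.198. With 3 control libraries the controls could not be split, so part of the excess may come from the shared controls.

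**Figure D3:**
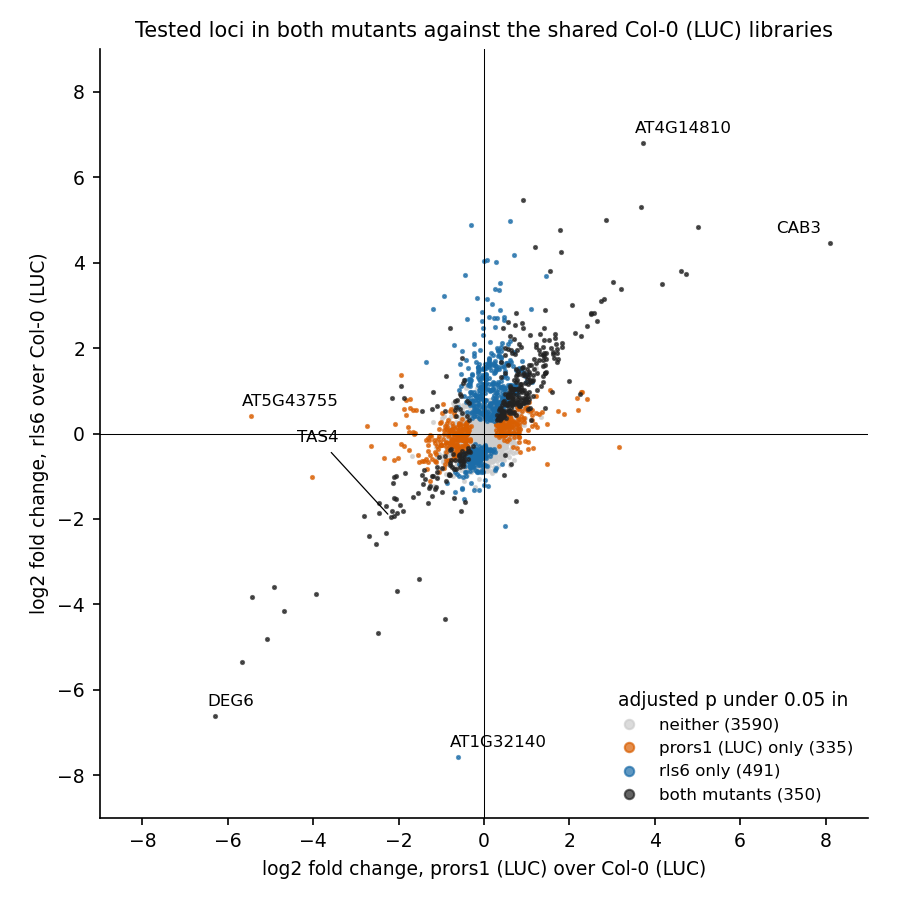
Log2 fold changes of the 4766 tested loci in prors1 (LUC) and rls6, each over the same Col-0 (LUC) libraries, on the log2(normalized reads + 1) scale, each point being a locus. There were 350 called in both mutants, 335 in prors1 (LUC) and not in rls6, and 491 in rls6 and not in prors1 (LUC), with AT5G43755 at -5.46 in prors1 (LUC) and AT1G32140 at -7.57 in rls6.

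Groups of loci can also be set out by how rls6 stood to both other genotypes. There were 319 genes higher in rls6 than in both, such as AT3G05025 and AT1G06417, and 65 lower than in both, such as AT1G32140 and ABH1. At 75 genes prors1 (LUC) was higher than Col-0 (LUC) and rls6 lower than prors1 (LUC), as at CAB3, and 10 of these were also called between rls6 and Col-0 (LUC), 4 of them as lower in rls6. At 159 genes prors1 (LUC) was lower and rls6 higher than prors1 (LUC), as at AT5G43755, and 37 of these were also called between rls6 and Col-0 (LUC), 26 of them as higher in rls6. A further 174 genes were higher in both mutants and 72 lower in both, with no call between the mutants, TAS4 being among the latter. Both calls behind the 75 and the 159 use the same prors1 (LUC) libraries, and both behind the 319 and the 65 the same rls6 libraries. Deviations of such shared libraries alone can place a gene in a group. No expected numbers were computed, so the counts do not show changes undone in rls6 or particular to it.

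The authors' deposited table holds 1 comparison, whose fold changes followed prors1 (LUC) over Col-0 (LUC) (Pearson r 0.998 over 1770 genes with a mean of at least 50 normalized reads). An adjusted p below 0.05 was given to 436 genes in the authors' deposited table, 239 higher and 197 lower. Of these, 402 were tested here and 401 were called here, all 401 in the same direction.

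**Figure D4:**
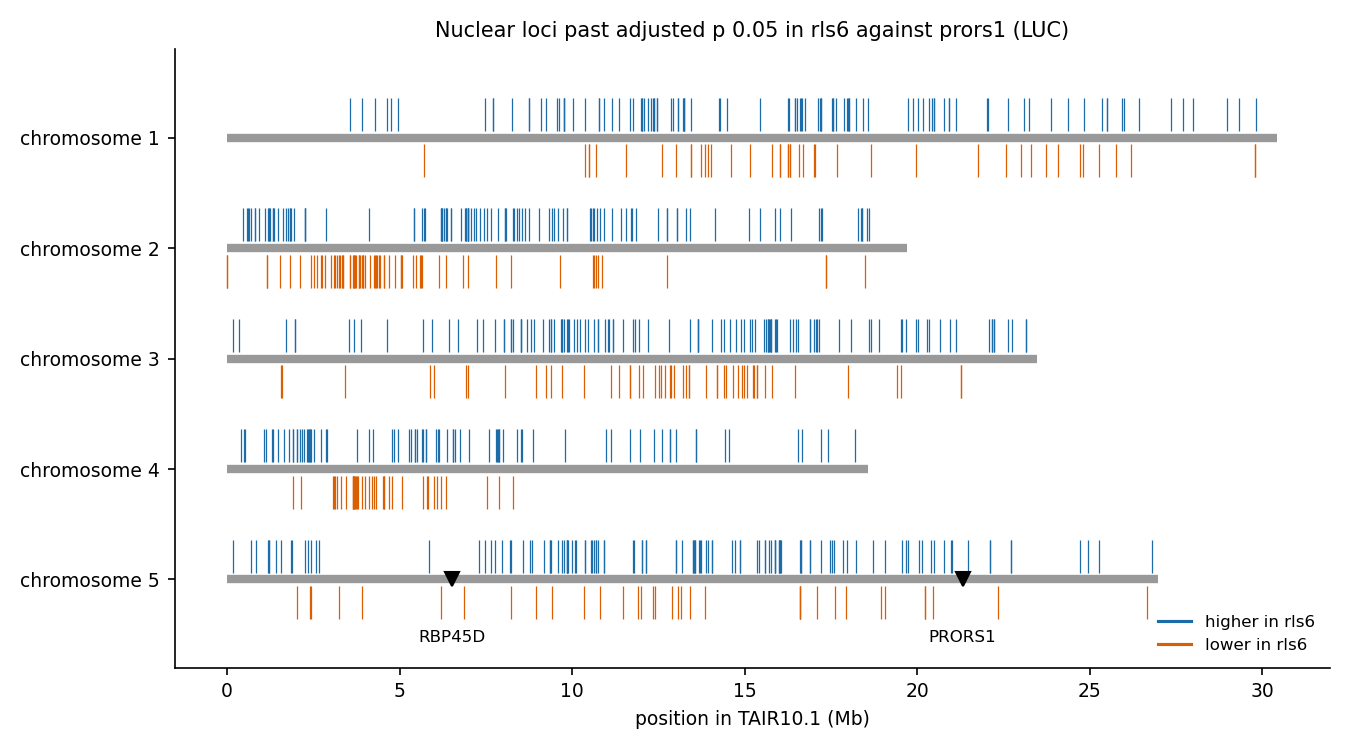
Positions in TAIR10.1, in Mb, of the 782 nuclear loci called between rls6 and prors1 (LUC) on the 5 chromosomes. Lines above a chromosome are the 542 loci higher in rls6, lines below it the 240 loci lower in rls6, and triangles mark RBP45D and PRORS1 on chromosome 5.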

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

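The tests against mitochondrial genes, against other copies of the light-harvesting gene and for a LUC transgene were chosen only after the result they bear on was seen. The others were set before their result was seen.

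At 30 genes prors1 (LUC) and rls6 went in opposite directions against the same Col-0 (LUC) libraries, each past adjusted p 0.05 with limma, which drew attention as a difference between the mutants. The 30 also passed the test between the mutants, by construction, since its fold change is the difference of the pair of opposite ones. Of these, 26 were lower in prors1 (LUC) and higher in rls6, 17 protein-coding genes, 7 pseudogenes and 2 long non-coding RNA genes, and 4 were the reverse. The largest of each kind are named here, chosen after their values were seen. The serine carboxypeptidase gene AT5G22860 averaged 34.5 ± 6.39 normalized reads (SD, n = 3) in Col-0 (LUC), 19.5 ± 4.03 in prors1 (LUC) and 194 ± 5.80 in rls6, a log2 fold change of 3.27 between the mutants. The F-box gene AT2G02240 (MEE66) averaged 26.1 ± 3.82, 6.48 ± 3.52 and 57.3 ± 3.62 (log2 fold change 3.06). In the other direction, the invertase and pectin methylesterase inhibitor gene AT5G46930 averaged 114 ± 17.5, 191 ± 14.5 and 37.7 ± 7.32 (log2 fold change -2.33), and the F-box gene AT1G67450 averaged 330 ± 63.6, 459 ± 94.1 and 167 ± 7.68 (log2 fold change -1.44).

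Of the 7746 genes at 0 in all 9 libraries, 2271 had a base mean above 0 in the authors' deposited table, the highest being 0.668. These base means stand in a column that the comparisons do not use. The table does not say which libraries they came from, and no explanation was tested.

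The chloroplast-encoded genes were higher in both mutants, with median log2 fold changes of 0.81 and 1.12, although neither group call was kept with an estimated correlation between genes (camera adjusted p = 0.0679 in prors1 (LUC) and 0.064 in rls6). The authors' size factors as the whole cause were argued against, since under 3 other scalings the median stayed at 0.80 or more (highest 1.13). A general rise of organelle fragments through RNA breakdown was argued against in rls6. There the upper 95% bootstrap bound of the mitochondrial median was 0.11, below the chloroplast median divided by 2, 0.56. The bootstrap drew genes and not libraries, so the bound does not cover the spread between libraries. With upper-quartile factors over all genes the medians in rls6 were 0.24 for mitochondrion-encoded and 1.39 for chloroplast-encoded genes. In prors1 (LUC) the bootstrap bound was 0.51 around a median of 0.41, and the chloroplast median divided by 2 was 0.41. Such breakdown may account for part of the rise there and cannot be told apart from an effect of the genotype. The genotype itself stays open in both mutants, untested beyond the comparisons given.

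Reads at AT1G29910 (CAB3) were 3085 over the prors1 (LUC) libraries, 258 over rls6 and 11 over Col-0 (LUC). Breakdown of photosynthesis mRNAs in general was argued against, since the other 24 genes of that list, CAB2 included, together reached at most 1.42 times the Col-0 (LUC) mean in a prors1 (LUC) library. CAB2 makes up most of that rise. Reads of another copy of the gene placed there cannot be told apart, because no more than 57.4% of the 21-base windows of AT1G29910 occur once in the reference and the handling of reads with several matches is not known. If LUC stands for a reporter transgene, sequence shared with it is a possible explanation that cannot be told apart here, since 0 entries of the table name a transgene. The name of Col-0 (LUC), with 11 reads, holds LUC as well, while that of rls6, with 258, does not. If the names are right about this, the presence of such sequence alone would not give the difference. An effect of the genotype also stays open, untested.

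Loci called between rls6 and prors1 (LUC) may lie in groups along the chromosomes. Pairs of loci 10 to 200 kb apart and called in the same direction numbered 981, against a median of 825 (95% range 774 to 882, highest 932) over 10000 shuffles within gene class and locus density (permutation p = 1e-04, the smallest these shuffles can give). A segment carried along with a mutated locus was tested within 3 Mb. The titles do not say that rls6 is mutated at RBP45D. Around RBP45D 21 of 83 tested loci were called between the mutants (odds ratio 1.68, 95% interval 0.968 to 2.82, Fisher's exact p = 0.0530), and around PRORS1 15 of 99 were called in prors1 (LUC) against Col-0 (LUC) (odds ratio 1.2, 0.639 to 2.11, Fisher's exact p = 0.544), and these intervals leave both a segment and none open. No biological explanation of the grouping was tested.

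Other splits of the 6 libraries of each comparison were too few, 10 with the real one, for a share under 0.05. The real splits gave 685, 841 and 802 called genes in prors1 (LUC) against Col-0 (LUC), rls6 against Col-0 (LUC) and rls6 against prors1 (LUC), the highest other split gave 0 in each, and 1 of the 10, the real one, was as large as the real one.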

How the results depend on the processing

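The edgeR, TMM, no-trend and all-gene upper-quartile settings were added after seeing the data, the last of them first run by mistake, and the other settings were chosen before. Over 22 settings of scaling, filter, tool, pseudocount and left-out library, no gene called in a comparison was called in the opposite direction. With DESeq2 the calls fell to 305, 503 and 419 in prors1 (LUC) against Col-0 (LUC), rls6 against Col-0 (LUC) and rls6 against prors1 (LUC), and with an absolute log2 fold change of at least 1 to 236, 385 and 326, by construction. Limma without a trend called 429 in prors1 (LUC), and 669 and 581 in the others. The cause of the lower DESeq2 and no-trend counts was not tested. Other settings stayed within 1.5 times of 685, 841 and 802. EdgeR called 674, 882 and 791, of which limma shared 653, 831 and 768. Leaving out 1 library gave 484 to 725, 644 to 907 and 602 to 851.

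The lists called were 3, 2 and 3 in the same order. With an estimated correlation they were 0, 1 and 1, and without organelle, rRNA and tRNA genes 1, 1 and 1, where the organelle lists are absent by construction. Fry called 4, 3 and 4, among them the trans-acting siRNA loci in prors1 (LUC) (adjusted p = 0.00169) and between the mutants (0.00818). The correlation of the mutants' fold changes, 0.566, was 0.535 without a filter and 0.568 to 0.600 without 1 Col-0 (LUC) library (highest without replicate 2), and the cause was not tested.

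Upper-quartile factors over all genes with a read, whose upper quartile is 2 or 3 reads, are not among the 22 settings. They gave 769, 1171 and 700 calls, with 632, 1104 and 603 of them higher, and raised the median of the tested genes to 0.20, 0.26 and 0.07. Under them the medians that turned were those of the pseudogenes (-0.00 to 0.18), trans-acting siRNA loci (-0.09 to 0.11) and secondary siRNA loci (-0.14 to 0.05) in prors1 (LUC), of the pseudogenes (-0.10 to 0.17), mitochondrion-encoded genes (-0.03 to 0.24, 2 higher) and secondary siRNA loci (-0.07 to 0.21) in rls6 against Col-0 (LUC), and of the silencing components (-0.07 to 0.02) between the mutants. The pseudogenes between the mutants went from -0.10 to -0.00. The chloroplast-encoded genes stayed higher in both mutants (0.99 and 1.39).

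Of 114 results for named genes, 95 were called. In at least 1 of the 22 settings 18 of these were lost and 2 others gained (AGO2 with no filter, adjusted p = 2.25e-09, and AGO3 without Col-0 (LUC) replicate 2), and 0 reversed. AGO2, in rls6 against Col-0 (LUC), had the same log2 fold change of 0.18 there as in the main fit (adjusted p = 0.525). Its values overlapped between these genotypes, so this gain is no sign of a larger change. Of the 48 largest changes 1 was lost, AT3G19880 with DESeq2. Genes with few reads limit precision, as the counting intervals show.

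The labels name no batch for the replicate numbers and not every same-numbered pair of libraries correlated above 0.1, so the numbers were not taken to pair the libraries. The correlations of same-numbered libraries were -0.0182 to 0.153, with 2 of 9 over 0.1, and of others -0.124 to 0.0323. In both other genotypes at once, 5 of the 9 libraries, not every one, correlated best with their own number. This is a hint from the data that leaves a shared batch neither shown nor excluded. With the number as a block, calls were 825, 967 and 909, holding all 685, 841 and 802, and the lists called were 3, 2 and 3.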

Other observations

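All tests in this part were chosen after the map of called loci, the trans-acting siRNA values or the overlaps with microRNA genes had been seen.

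Called loci were counted inside and outside the regions where pseudogenes are dense, without a test of the difference. In the 5 Mb window with most annotated pseudogenes on each chromosome (12.6 to 17.6, 1.6 to 6.6, 11 to 16, 1.3 to 6.3 and 9.7 to 14.7 Mb on chromosomes 1 to 5), 127 of 2826 tested nuclear loci (4.49%) were higher in rls6 than in Col-0 (LUC), against 381 of 1800 elsewhere (21.2%). Lower were 139 inside (4.92%) and 94 outside (5.22%). Between rls6 and prors1 (LUC), 6.05% inside and 20.6% outside were higher, and 5.38% and 4.89% lower. In prors1 (LUC) against Col-0 (LUC) 3.15% inside and 11.1% outside were higher and 4.07% and 11% lower. The median log2 fold change of rls6 against Col-0 (LUC) was -0.11 inside and 0.11 outside.

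The shares depend on the scaling. Higher loci in rls6 against Col-0 (LUC) were 3.62% inside and 17.8% outside with upper-quartile factors over the tested genes, and 11.9% and 36.2% with such factors over all 29590 genes with a read, first run by mistake in place of the former and then kept as an added setting. Lower loci were 9.72% inside and 8.10% outside with the former and 0.562% and 2.69% with the latter, so that their order turned. Between rls6 and prors1 (LUC), lower loci were 8.96% inside and 6.58% outside with the former. With the latter they were 1.62% and 2.63%, turned as well. The upper quartile over all genes was 2 reads in 7 libraries and 3 in 2, so its factors rest on steps of 1 read.

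Among pseudogenes alone, 2.76% inside and 11.7% outside were higher in rls6 than in Col-0 (LUC), and 5.25% and 2.82% lower. Between the mutants 4.45% and 12% were higher and 5.47% and 4.89% lower, and in prors1 (LUC) against Col-0 (LUC) 2.09% and 6.95% were higher and 3.65% and 6.20% lower. In rls6 against Col-0 (LUC), upper-quartile factors over all genes gave 9.15% inside and 24.4% outside as higher and 0.442% and 0% as lower. Neighbouring loci are not independent, so no p is given.

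TAS4, which fell in both mutants, yields a trans-acting siRNA directed at the anthocyanin regulators PAP1, PAP2 and MYB113. These 3 loci together had 81 reads in Col-0 (LUC), 30 in prors1 (LUC) and 29 in rls6, or 23.1 ± 7.58, 10.2 ± 3.31 and 9.15 ± 1.22 normalized reads (SD, n = 3). The ratio to Col-0 (LUC) was 0.441 in prors1 (LUC) (95% counting interval 0.271 to 0.657) and 0.396 in rls6 (0.244 to 0.598), each with an exact permutation p of 0.1, the smallest 3 against 3 allows, and an adjusted p of 0.15. The ratio of rls6 to prors1 (LUC) was 0.897 (exact p = 0.6).

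Genes with a microRNA gene on the opposite strand passed the minimum of reads more often than others. Of 36 such genes 17 were tested, against 4609 of 37015 without one (odds ratio 6.29, 95% interval 3.07 to 12.8, Fisher's exact test p = 3.42e-07). Of the 21-base windows of the light-harvesting genes, 57.7% of AT1G29920, 55.6% of AT1G29930 and 70.7% of AT2G34430 occur once in the reference.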
